A study of Mus musculus with 8 samples.

How the data were processed

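The samples were 8 whole-lung total RNA preparations, 4 from wild-type and 4 from lung-restricted Ggps1 knockout C57BL/6 mice, all 12 h after LPS, and the series' design text counts 4 mice per group. Per the labels' protocols, RNA integrity was checked on a Bioanalyzer and cRNA was labelled with Cy3 for single-colour Agilent arrays. Per the file headers and the submitters' processing notes, the scans were read with Agilent Feature Extraction 10.7.1.1, and the probe coordinates in the files are on build mm9. The deposited scanner files give intensity values for each spot, including a background-subtracted and detrended processed signal in which Feature Extraction puts a surrogate value in place of signals it cannot tell from background. The deposited value table holds log2 values by the authors, 1 column per array. Set against the scanner signals, its columns correlated with log2 processed signal at r above 0.99 over probes, all had a median of 5.63 and shared a common distribution, as quantile normalization gives. Its scale and centring were therefore taken from the files, and no ratio direction arises.

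From each array, control spots and spots marked as outliers were left out (154 to 245 outlier spots per array, and 21 probes with no usable spot on an array). Spots of 1 probe were averaged, and log2 processed signal was set relative to the 75th percentile of the array over 55681 probes. No probe was saturated. A probe was kept when it was well above background on 3 or more of the 4 arrays of a group, and of several probes with 1 gene name the one with the highest mean was used, which left 24464 of 36163 gene names. Percent of spots well above background was 63.6 ± 1.8 in wild-type and 59.8 ± 1.5 in knockout samples (SD, n = 4 per group, exact permutation p = 0.0571). The percent of probes at the surrogate value was 17.4 ± 2.2 in wild-type and 23.2 ± 1.7 in knockout samples (SD, n = 4 per group, exact permutation p = 0.0286). For arrays the number of samples limits the precision. Gene names come from the array files. Of the probes, 26576 were matched by RefSeq accession, 2607 by symbol and 492 by a synonym to a table of the GRCm38.p6 assembly, which was used for names only, and 26006 kept the name in the file.

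Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The adjusted p-values in the text are from this fit unless camera is named. Signed values are knockout minus wild-type on the log2 scale. Where a gene was not well above background on any array of a group, the fold is a lower bound: the mean of the brighter group against the dimmer group's mean of, per array, the higher of the lowest signal well above background and the probe's own signal. Gene lists were tested with camera at its preset correlation of 0.01 (lists of 5 or more measured genes, 28 of 29, adjusted over the lists), and each list's members were also adjusted over the list alone. Exact permutation tests on list means and single values used all ways of dividing the 8 samples into 4 and 4 and were two-sided. The groups, tests, gene lists, most alternatives and the rule for naming genes were set before the data were examined. The rule names the targeted gene, up to 12 genes per direction among those past the threshold with separate groups and a proper gene symbol, 11 genes of the inflammasome, cytokine, neutrophil and surfactant programmes, and up to 4 members of each list with the smallest p. AW112010, Chil6, TC1728321 and the platelet and cartilage lists were chosen after the values were seen.

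The gene test was run on simulated data with the means and spreads of these arrays and 200 of 24464 genes changed. In that simulation it recovered 30% of the genes changed by 0.5 on the log2 scale, 60% of those changed by 1, 90% of those changed by 2 and 96% of those changed by 4, with 16 false calls. These rates hold for that share of changed genes and for independent genes, and may differ in the real data. Camera called 0 of 28 lists in simulated data without a change and the 1 list that was shifted by 0.5, with genes simulated as independent.

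Alternatives were normexp background correction with an offset of 50 on mean and background signals, quantile normalization, median centring, no background filter, a filter on all 8 arrays and the deposited value table. Further ones were the replicate number as a block, the mean of a gene's probes, each probe on its own, an intensity trend in the variance, array weights, other thresholds, camera with an estimated correlation, fry, exact permutation of list means, the cardiac muscle score as a covariate, and leaving out each sample. A block for the slide was not run because there was 1 slide. Figures were drawn with matplotlib 3.10.9.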

Results

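Whole-lung RNA was compared between wild-type C57BL/6 mice and mice with a lung-restricted knockout of Ggps1, all taken 12 h after lipopolysaccharide (LPS). LPS is the bacterial outer-membrane component that is sensed through TLR4 and injures the lung. Ggps1 encodes geranylgeranyl diphosphate synthase, which makes the lipid that is attached to many small GTPases. Each group had 4 mice, each on its own single-colour Agilent array. The series title ties the comparison to acute lung injury and to the NLRP3 inflammasome, the complex that activates caspase-1 and matures interleukin-1β and interleukin-18. Between 58.1% and 65.3% of the spots of an array were well above background, and 24464 genes were tested. All 8 arrays lay on 1 slide, with the wild-type samples in slide row 1 and the knockout samples in row 2, so the position on the slide and the genotype cannot be told apart. Mice without LPS were not analysed here, so the values compare genotypes under LPS and not the response to LPS.

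Ggps1 mRNA was at nearly equal levels in the knockout and wild-type lungs. Its brightest probe (mm9 chromosome 13, 14145961 to 14146020) read 1.26, 1.34, 1.26 and 1.40 in wild-type replicates 1 to 4 and 1.32, 1.24, 1.22 and 1.24 in knockout replicates 1 to 4, as log2 signal relative to the 75th percentile of the array. The difference, knockout minus wild-type, was -0.06 ± 0.068 (SE; limma, adjusted p = 0.613), and with the mean of all Ggps1 probes it was 0.0054. Of the other probes for the gene, A_51_P469902 differed by -0.12 ± 0.15 and A_55_P2170569 by 0.19 ± 0.089 (SE), with exact permutation p = 0.429 and 0.0857. Which part of Ggps1 was deleted is not given in the sources used here, and whole lung holds cells that a tissue-restricted deletion spares, so these probes do not check the genotype labels.

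Inflammasome genes were lower in the knockout lungs as a group, by a median of 1.48-fold, as were monocyte and interstitial macrophage markers (1.55-fold), alveolar type 1 cell markers (1.33-fold) and lymphocyte markers (1.27-fold). Markers of ciliated cells (1.43-fold) and club cells (2.32-fold) of the airways, cell cycle genes (1.40-fold) and clock genes (1.25-fold) were higher. Each of these 8 lists was called by camera at its preset correlation and lost its call when the correlation was estimated (adjusted p = 0.53 with an estimated correlation). Few single genes passed the test. Of 24464 genes, 8 rose and 7 fell (limma, Benjamini-Hochberg adjusted p under 0.05), and for all 15 the 4 knockout values lay apart from the 4 wild-type values. Of the 7 that fell, only Gp1ba was well above background on all 4 knockout arrays. Centring the arrays on their medians gave 6 genes that rose and 11 that fell.

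Of the inflammasome list, 18 of 21 measured members were lower in the knockout lungs (median log2 difference -0.56; camera, adjusted p = 0.00437). The mean over its members differed by -0.57 ± 0.21 (SE, n = 4 per group, exact permutation p = 0.0571). This call was lost when the correlation between the members was estimated (adjusted p = 0.53 with an estimated correlation). Adjusted over the list alone, 1 member fell, Aim2, the cytosolic DNA sensor, which went from -3.32 ± 0.19 to -4.00 ± 0.24 (SD, n = 4 per group). Over all genes tested, 0 members passed, while 7 were lower at an unadjusted p under 0.05. Nlrp3 itself differed by -1.37 ± 0.46 (SE) and did not pass (limma, adjusted p = 0.137), nor did Casp1 at -0.49 ± 0.16 (adjusted p = 0.125 with limma). The precursors of the released cytokines, Il1b and Il18, differed by -0.74 ± 0.38 and -0.79 ± 0.52, and the adaptor Pycard by -0.26 ± 0.13 (SE), none of them past the threshold. Nlrp1b stood at -2.37 ± 1.53 in wild-type and -4.33 ± 0.49 in knockout lungs (SD, n = 4 per group), with wild-type replicate 1 at -0.10, far above the other wild-type samples. With normexp background correction the differences shrank to -0.25 for Aim2, -0.89 for Nlrp1b and -0.87 for Nlrp3, while Casp1 (-0.50) and Il1b (-0.76) kept theirs.

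**Figure D1:**
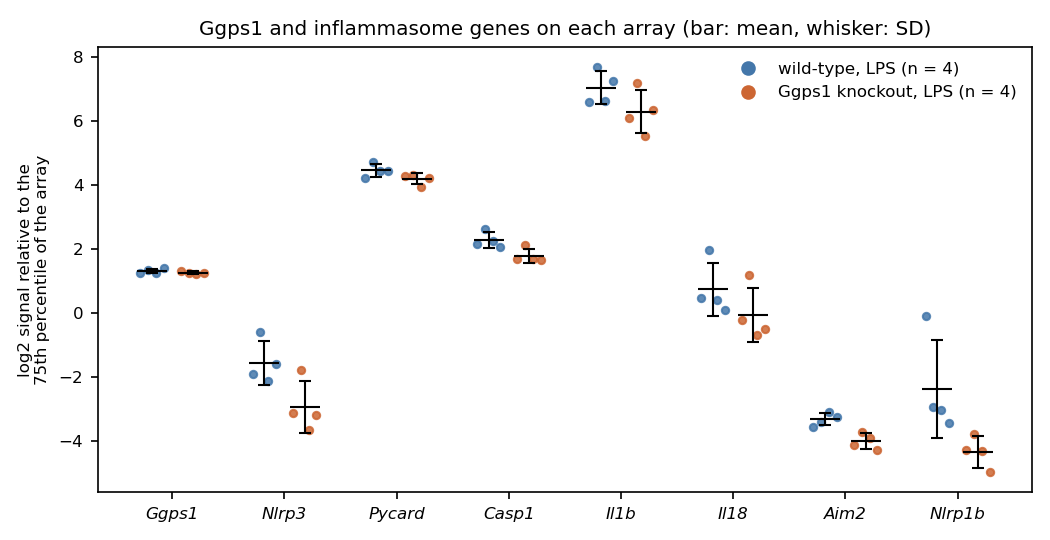
Log2 signal of Ggps1 and of 7 inflammasome genes relative to the 75th percentile of each array, with 1 point per array (wild-type in blue, knockout in orange, n = 4 each), a bar at the mean and whiskers of 1 SD. Ggps1 lies between 1.22 and 1.40 on all 8 arrays, and the knockout means of the other 7 genes lie below the wild-type means, by 0.26 (Pycard) to 1.96 (Nlrp1b) on the log2 scale.

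Cytokine, chemokine and NF-κB target genes that LPS induces were lower in 31 of 39 measured cases (median -0.41; camera, adjusted p = 0.012, and adjusted p = 0.631 with an estimated correlation). The list mean differed by -0.44 ± 0.28 (SE, n = 4 per group, exact permutation p = 0.2). No member passed in either adjustment, and 9 were lower and 1 higher at an unadjusted p under 0.05. Tnf differed by -0.79 ± 0.40, Il6 by -0.41 ± 0.57, the endothelial adhesion molecule Sele by -1.14 ± 0.34 and the monocyte chemoattractant Ccl7 by -1.05 ± 0.35 (SE). Cxcl5, an epithelial chemoattractant of neutrophils, went the other way at 0.95 ± 0.25. Without wild-type replicate 2 the median was -0.26 and the call was lost (camera, adjusted p = 0.154). The call was also lost without wild-type replicate 4 (median -0.31; camera, adjusted p = 0.0758), knockout replicate 3 (median -0.34, adjusted p = 0.0531) or knockout replicate 4 (median -0.35, adjusted p = 0.0587), though the size moved less there. Components of TLR4 signalling were lower in 21 of 24 cases (median -0.19; camera, adjusted p = 0.0073, and adjusted p = 0.53 with an estimated correlation). Of these, 2 fell when adjusted over the list alone, the receptor Tlr4 by -0.54 ± 0.12 and the kinase Irak4 by -0.51 ± 0.097 (SE), and over all genes 0 did. Immediate early genes were lower in 15 of 16 cases (median -0.41; camera, adjusted p = 0.00042, and adjusted p = 0.53 with an estimated correlation), with Atf3 (-0.81 ± 0.19) and Fos (-0.67 ± 0.18) falling when adjusted over the list alone.

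Of the 28 lists tested, that of monocyte and interstitial macrophage markers had the most members that fell. Of 18 measured, 17 were lower and 14 fell when adjusted over the list alone, with 0 past the threshold over all genes. The median was 1.55-fold lower, and the list mean differed by -0.62 ± 0.14 (SE, n = 4 per group, exact permutation p = 0.0286, the smallest that 4 against 4 allows). Plac8 differed by -0.84 ± 0.16, the IgG receptor Fcgr1 by -1.03 ± 0.22, Treml4 by -1.15 ± 0.26 and the growth factor receptor Csf1r by -0.76 ± 0.18 (SE). Camera gave an adjusted p of 9.98e-07 for the list and an adjusted p of 0.53 with an estimated correlation. Lymphocyte markers were lower in 21 of 23 cases (median -0.34; camera, adjusted p = 0.000588, and adjusted p = 0.53 with an estimated correlation), and the natural killer cell receptor Ncr1 (-0.95 ± 0.24, and -0.46 with normexp) was among 2 that fell when adjusted over the list alone. Alveolar macrophage markers split. Ear1 (-1.12 ± 0.18), Ear2 (from 4.65 to 3.65) and Fabp1 (-1.47 ± 0.27, and -0.85 with normexp) were among 4 that fell when adjusted over the list alone. Plet1 rose (0.68 ± 0.17), and the list of 16 did not shift (camera, adjusted p = 0.276). Neutrophil markers did not shift either (24 measured, median -0.32; camera, adjusted p = 0.153). With the cardiac muscle score of each sample as a covariate, a setting chosen after the values were seen, they were called lower (median -0.46; camera, adjusted p = 0.00142, and adjusted p = 0.55 with an estimated correlation), the list mean going from -0.19 ± 0.18 to -0.41 ± 0.097 (SE). The abundant neutrophil proteins S100a8 (-0.04 ± 0.091) and S100a9 (0.11 ± 0.072, and negative with quantile normalization and in the deposited value table) were close to equal, and Mpo differed by 0.66 ± 0.41. The chemokine receptor Cxcr2 fell from 3.37 ± 0.46 to 2.27 ± 0.27 (SD) when adjusted over the list alone.

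Both airway epithelial lists were higher in the knockout lungs by camera. By exact permutation, their list means differed with p = 0.0571 (ciliated) and p = 0.2 (club). The club mean of knockout replicate 3 (1.78) lay below those of wild-type replicates 2 (2.90) and 3 (3.63). Ciliated cell markers were higher in 22 of 24 cases (median 1.43-fold; camera, adjusted p = 6.41e-07, and adjusted p = 0.53 with an estimated correlation). Adjusted over the list alone 9 rose, among them Foxj1, the transcription factor of motile cilia (0.59 ± 0.13), Drc1 (0.73 ± 0.14), Dnah9 (0.86 ± 0.21) and Cdhr3 (1.18 ± 0.27), and over all genes 0 did. Club and secretory cell markers were higher in 19 of 21 cases (median 1.21; camera, adjusted p = 9.05e-05, and adjusted p = 0.53 with an estimated correlation). Only Cbr2 rose when adjusted over the list alone (0.69 ± 0.12), and Cyp2f2 (0.70 ± 0.20) and Scgb3a2 (1.02 ± 0.40) did not pass. Without knockout replicate 4 the medians were 0.32 for the ciliated and 0.72 for the club list. Epithelial junction genes were higher in 16 of 22 cases (median 0.14; camera, adjusted p = 0.0109, and adjusted p = 0.53 with an estimated correlation), led by Tjp3, a tight junction scaffold (0.83 ± 0.14), the 1 member that rose when adjusted over the list alone. This call was lost without wild-type replicate 2 (median 0.073; camera, adjusted p = 0.0564) and with no filter on dim probes (adjusted p = 0.0872). The median was 0.091 without knockout replicate 3.

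Markers of tissue other than lung parenchyma moved with these lists. Cardiac muscle markers, which mark heart and the muscle sleeves of the pulmonary veins, were higher in 14 of 14 cases (median 1.70; camera, adjusted p = 0.00289, and adjusted p = 0.601 with an estimated correlation), and 0 passed in either adjustment. Their mean lay at 3.41 in wild-type replicate 2 and between -1.21 and 0.47 in the other wild-type samples, and at 1.60, 3.85, 0.66 and 3.49 in knockout replicates 1 to 4. By exact permutation, the difference of the cardiac mean had p = 0.143. The median was 1.02 without wild-type replicate 1 (camera, adjusted p = 0.0615) and 2.65 without wild-type replicate 2. Smooth muscle markers were higher in 10 of 11 cases (median 0.51; camera, adjusted p = 0.00437, and adjusted p = 0.53 with an estimated correlation), with Myh11 at 1.08 ± 0.47 and Synpo2 at 1.76 ± 0.53 (SE), and 0 passed in either adjustment. Markers of fat and thymus were higher in 9 of 11 cases (median 1.44; camera, adjusted p = 0.0619). The T cell gene Cd8b1 fell and Lep rose when adjusted over the list alone. Lep was not well above background in wild-type lungs and was on average at least 3.98-fold higher in knockout lungs (limma, adjusted p = 0.0988 over all genes). Knockout replicate 3, at -6.87, lay beside the highest wild-type sample at -6.88, and the other knockout samples at -3.18 to -1.14. With normexp the log2 difference of Lep was 1.32, below that bound. Alveolar type 1 markers were lower in 18 of 18 cases (median -0.41, camera adjusted p = 0.000196, exact permutation p of the list mean 0.114). Camera with an estimated correlation gave an adjusted p of 0.53. Igfbp2 differed by -1.28 ± 0.30 and Aqp5 by -0.44 ± 0.15 (SE), and 0 members passed in either adjustment. With the same cardiac covariate, the difference of the alveolar type 1 mean went from -0.57 ± 0.26 to -0.28 ± 0.18, that of the fat and thymus mean from 1.58 ± 1.16 to 0.28 ± 0.78, that of the club mean from 1.39 ± 0.95 to 0.60 ± 0.93, and that of the ciliated mean from 0.52 ± 0.20 to 0.51 ± 0.25 (SE). The smooth muscle list lost its call with it (mean 0.68 ± 0.40 to 0.45 ± 0.45, SE; median 0.25; camera, adjusted p = 0.099), while endothelial markers were called higher (mean 0.13 ± 0.052; camera, adjusted p = 0.0385, and adjusted p = 0.55 with an estimated correlation). The LPS-induced cytokine mean went from -0.44 ± 0.28 to -0.76 ± 0.20, the clock mean from 0.36 ± 0.10 to 0.47 ± 0.068 and the junction mean from 0.23 ± 0.051 to 0.27 ± 0.053 (SE), and all 3 lists kept their calls (adjusted p = 0.55, 0.237 and 0.237 with an estimated correlation).

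**Figure D2:**
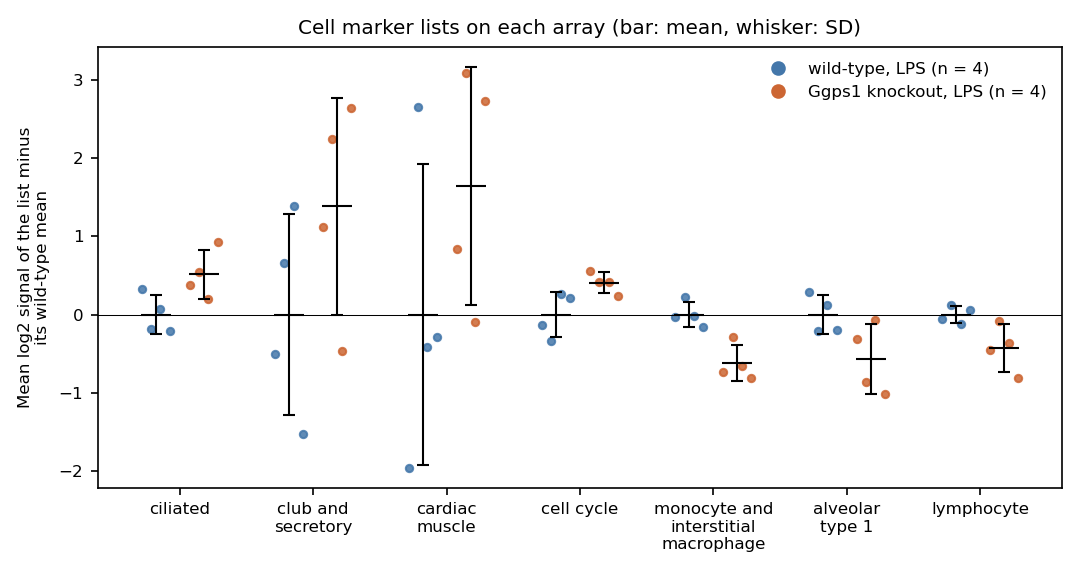
Mean log2 signal of 7 gene lists on each array, minus the wild-type mean of that list, with 1 point per array (wild-type in blue, knockout in orange, n = 4 each), a bar at the group mean and whiskers of 1 SD. The 4 knockout samples lie below all wild-type samples for monocyte and interstitial macrophage markers (difference -0.62), while the cardiac and club lists spread widely within both groups.

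Cell cycle genes were higher in 20 of 21 cases (median 1.40-fold; camera, adjusted p = 1.84e-06, and adjusted p = 0.53 with an estimated correlation). Adjusted over the list alone 6 rose, including Melk (0.56 ± 0.11, and 0.37 with normexp), Birc5 (0.73 ± 0.19), Cenpe (0.58 ± 0.17) and Aurka (0.48 ± 0.14, SE), and over all genes 0 did. Circadian clock genes were higher in 12 of 16 cases (median 0.32, and 0.19 without knockout replicate 3; camera, adjusted p = 0.00631, and adjusted p = 0.53 with an estimated correlation). Adjusted over the list alone 3 rose, Dbp (1.37 ± 0.25), Nr1d1 (1.22 ± 0.29) and Nr1d2 (0.85 ± 0.19), which are transcribed in phase with each other as direct targets of the clock. Cry2 differed by 0.65 ± 0.21 and did not pass.

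The named genes among the 15 that changed include a pair made in platelets. Gp1ba, the platelet receptor for von Willebrand factor, fell by 1.32 ± 0.15 (limma, adjusted p = 0.0456), and Ly6g6f, a platelet surface protein, fell by 2.16 ± 0.20 (adjusted p = 0.0315 with limma, well above background on 2 of 4 knockout arrays). Chrna7, the α7 nicotinic acetylcholine receptor subunit, was not well above background on any knockout array and was at least 2.39-fold lower there (limma, adjusted p = 0.0456). Naif1 fell as well (limma, adjusted p = 0.0456) but was not well above background in the knockout lungs and has no fold to give. Cacng7, a calcium channel auxiliary subunit, rose from -2.25 ± 0.11 to -1.22 ± 0.11 (SD, n = 4 per group; limma, adjusted p = 0.0315), and Cblc, a ubiquitin ligase of the CBL family, rose from 1.34 ± 0.081 to 2.16 ± 0.13 (SD, n = 4 per group; limma, adjusted p = 0.0416). Picked out after the values were seen, AW112010, an LPS-inducible macrophage transcript, rose by 0.90 ± 0.087, and Chil6, a chitinase-like gene, by 2.35 ± 0.24 (SE). With normexp background correction the differences of the dim genes shrank, to -0.86 for Ly6g6f, -0.48 for Chrna7 and -0.14 for Naif1. That of Chrna7 is smaller than its bound of 2.39-fold, and Naif1 no longer passed (limma, adjusted p = 0.308). Averaging the probes of a gene moved Cacng7 to 0.54 (adjusted p = 0.0544 with limma). Of the settings tried, Cacng7 passed in 12 of 18, Ly6g6f in 12 of 17 and Chrna7 in 9 of 17. Cblc passed in 8 of 18, Gp1ba in 7 of 18 and Naif1 in 6 of 17. AW112010 and Chil6 passed in 11 of 18 each. TC1728321, which has no gene symbol and was also picked out after the values were seen, had the smallest adjusted p. It rose by 1.67 ± 0.098 (SE, limma adjusted p = 0.00355) and passed in 18 of 18 settings.

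Camera called none of the remaining lists. Genes of the pathway that holds Ggps1, mevalonate and cholesterol synthesis, had a median difference of -0.02 over 24 members (camera, adjusted p = 0.798), with Srebf2 at -0.70 ± 0.17 (SE). Prenyltransferases and small GTPases, the users of its product, were lower in 25 of 34 cases by a median of -0.07 (camera, adjusted p = 0.0583), which was -0.04 with quantile normalization and -0.12 with median centring. Their list mean was lower in every knockout sample than in every wild-type sample, by -0.14 ± 0.028 (SE, n = 4 per group, exact permutation p = 0.0286), and the groups were as fully apart in 4 other lists (monocyte and immediate early, lower, and clock and junction, higher). Adjusted over the lists, the exact permutation p was 0.166 for each of the 5. Among its members, Rac2 differed by -0.73 ± 0.22, Rap1a by -0.59 ± 0.19 (-0.26 with normexp) and Arhgdib by -0.57 ± 0.13 (SE). Interferon-stimulated genes did not shift (36 measured, median -0.13; camera, adjusted p = 0.422), though Cxcl9 rose by 1.71 ± 0.34 when adjusted over the list alone and Oas2 stood at -1.02 ± 0.24. Antioxidant genes did not shift as a list of 26 (median 0.09; camera, adjusted p = 0.177). Adjusted over the list alone 5 rose, among them Nqo1 (0.49 ± 0.11), Gpx2 (1.08 ± 0.27) and Gsta4 (0.82 ± 0.18), and 4 fell, among them Cybb, the phagocyte oxidase subunit (-1.08 ± 0.25). Alveolar type 2 markers were lower in 13 of 18 cases (median -0.19; camera, adjusted p = 0.161), with Cxcl15 falling by 0.79 ± 0.18 when adjusted over the list alone and Sftpc at 0.09 ± 0.10 (negative with quantile normalization and in the deposited value table). With the cardiac covariate the list median turned to 0.03 and the mean went from -0.22 ± 0.15 to -0.09 ± 0.13 (SE). Endothelial markers had a median of -0.03 (23 measured; camera, adjusted p = 0.665), which turned positive with quantile normalization and in the deposited value table, and Calcrl fell by 1.42 ± 0.27 when adjusted over the list alone. Unfolded protein and amino acid stress genes had a median of -0.05 (camera, adjusted p = 0.665), and Herpud1 rose by 0.32 ± 0.087 while Edem1 and Atf3 fell, adjusted over the list alone. Fatty acid and surfactant lipid synthesis had a median of -0.06 (camera, adjusted p = 0.745) and fibroblast and matrix genes one of -0.20 (camera, adjusted p = 0.243). Erythroid markers were lower in 8 of 9 cases (median -0.55; camera, adjusted p = 0.0573). The 13 measured neighbours of Ggps1 on chromosome 13 had a median of -0.05 and a mean of 0.07 (camera, adjusted p = 0.512), and with the cardiac covariate a median of -0.18 and a mean of -0.08 ± 0.038 (SE). Of the sex-linked genes 3 were measured, too few for a set test, with a median of 0.06 that turned negative with median centring. The Y-linked gene Eif2s3y differed by 0.09 ± 0.10 (SE).

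**Figure D3:**
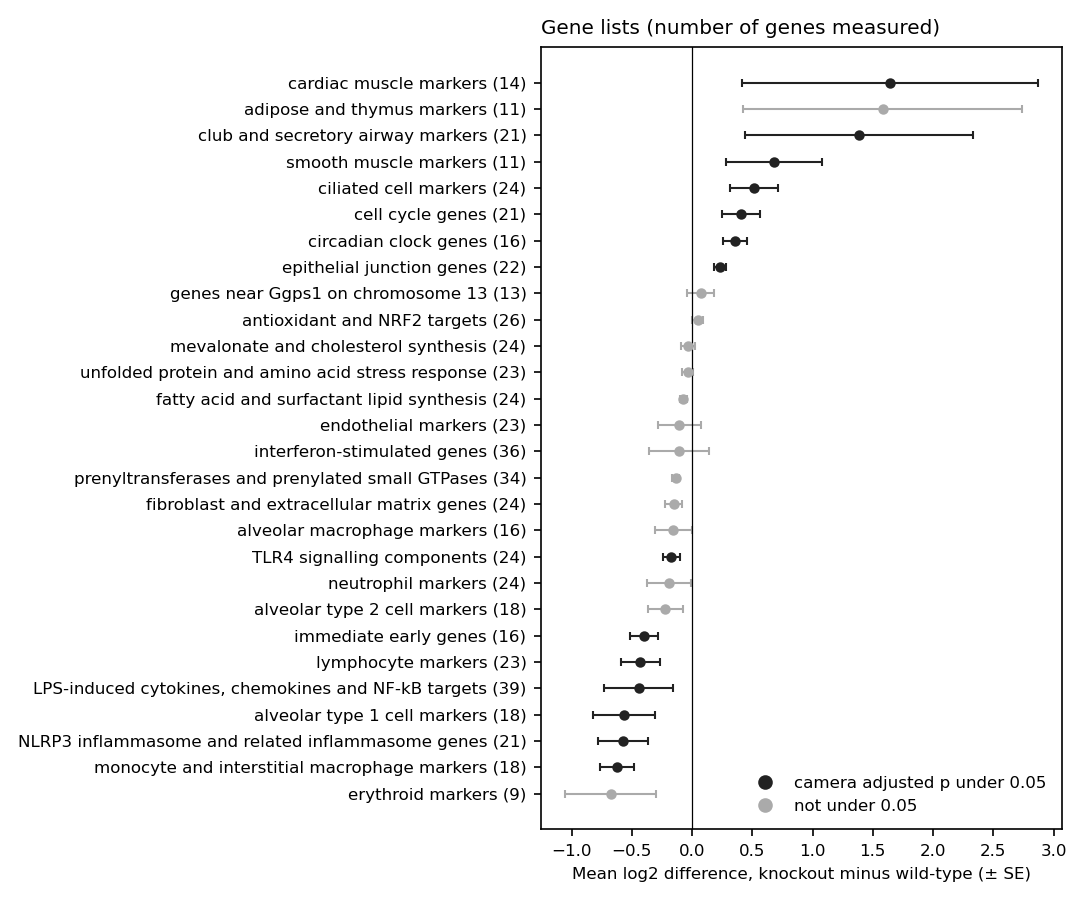
Mean log2 difference, knockout minus wild-type, of each of the 28 gene lists tested, with whiskers of 1 SE over 4 samples per group, and black points where the camera adjusted p was under 0.05. Of the 14 black points 7 lie above 0 and 7 below, and the muscle, club and fat lists have the widest whiskers.

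The number of changed genes depended on the arrays, the filter and the model: it was 2, 1, 4 and 22 without wild-type replicates 1 to 4, 1, 1, 24 and 10 without knockout replicates 1 to 4, and 3522 with no filter on dim probes. On the same genes it was 512 with normexp background correction (229 higher and 283 lower), 417 with an intensity trend (160 and 257) and 302 with array weights (142 and 160). At an unadjusted p under 0.05, 5761 genes differed (2487 higher and 3274 lower). In 15.3% of genes the groups did not overlap, where chance gives 2.86% on average over all splits of the 8 samples. A single split can lie far from such an average, since genes vary together across the arrays. At an unadjusted p under 0.05 the other splits gave from 284 to 3680 genes. The spread of the 2.86% was not measured, and slide row goes with genotype.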

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

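In 314 groups of 4 values (list means, named genes and array measures), the highest or lowest sample was set against the rest by Dixon's criterion for 4 samples, and 9 stood out, where chance gives about 1 in 20, or 15.7. The scan left out 3 genes whose results are not reported here. All values here are log2 signal relative to the 75th percentile of the array. Among wild-type samples, replicate 1 stood apart for Nlrp1b at -0.10 (the others -3.43 to -2.93) and for Sele at -0.75 (0.29 to 0.44). Wild-type replicate 2 stood apart for the mean of the epithelial junction list at 1.06 (1.21 to 1.24). Among knockout samples, replicate 2 was high for Casp1 at 2.13 (1.67 to 1.69), for Ccl7 at 4.10 (2.62 to 2.84) and for Treml4 at 1.21 (0.16 to 0.23). Knockout replicate 3 was high for Cblc at 2.35 (2.07 to 2.12) and for Lpin1, a phosphatidate phosphatase, at -0.56 (-0.88 to -0.86), and knockout replicate 1 was high for Fabp1 at -2.78 (-3.68 to -3.59).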

How the results depend on the processing

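The alternatives chosen after seeing the data were the adjusted p under 0.10, normexp with no filter, the exact permutation of list means and the cardiac covariate. The count of 15 changed genes was 13 with quantile normalization or the value table, 17 with median centring and 22 with each probe tested alone. It was 512 with normexp background, 3522 with no background filter, 142 with normexp and no filter, 126 when filtered on all arrays, and 6 with the mean of a gene's probes. It was 417 with an intensity trend, 302 with array weights, 1817 at an adjusted p under 0.10, 490 at an unadjusted p under 0.05 with at least a 2-fold change, 1854 with the cardiac score as a covariate, and 1 to 24 with single samples left out. Apart from the setting with no filter, the cause was not tested. The count of 14 shifted lists, out of 28 tested, was 18 with normexp (7 higher and 11 lower, against 7 and 7), 17 with no filter (6 and 11) or the replicate block (7 and 10), 13 to 17 with single samples left out (12 to 14 of them among the 14), 5 by exact permutation of list means at an unadjusted p under 0.05 (4 among the 14), and 0 with camera at an estimated correlation or with fry (fry's test of change in either direction called 16). The median of the inflammasome list, -0.56, lost its call with an estimated correlation (adjusted p = 0.53), with fry (adjusted p = 0.12) and by exact permutation (p = 0.0571), and kept it in the other settings, with medians of -0.76 to -0.38 as samples were left out. The Ggps1 difference turned to 0.0054 with the mean of its probes and lay between -0.08 and -0.03 as samples were left out. Whether the replicate numbers pair animals is not known, and in both groups the number equals the slide column. With the number as a block 43 genes passed (10 higher and 33 lower, 7 of them among the 15). Same-numbered samples deviated from their group means with correlations of 0.13, 0.47, 0.01 and -0.29, which do not settle the pairing. The endothelial list, not called in the main setting (median -0.03), was called higher with the cardiac covariate (median 0.14, camera adjusted p = 0.0385). That call was lost with an estimated correlation (camera, adjusted p = 0.55). Among the results scored, no other reversed past its threshold. The genes and lists can be no more precise than the signal allows: dim probes sit near background, and their fold depends on its correction.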

Other observations

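The tests of the floor, of dilution in both forms, and of the splits for gene lists, for genes at an unadjusted p under 0.05 and for the setting with no filter were chosen only after the result was seen, as were the platelet and cartilage lists.

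Platelet transcripts formed a further group that was lower in the knockout lungs. Of 15 platelet genes other than Gp1ba, Gp1bb and Ly6g6f, 15 were lower and 12 fell when adjusted over the list alone, and 0 passed over all genes. Gp9 and Gp5, partners of Gp1ba in the von Willebrand factor receptor, differed by -1.20 ± 0.22 and -1.08 ± 0.16, the ADP receptor P2ry12 by -1.22 ± 0.21, and the granule chemokines Ppbp and Pf4 by -1.19 ± 0.25 and -0.57 ± 0.18 (SE). The median was -0.98, and camera gave an unadjusted p of 2.22e-09 and an unadjusted p of 0.0793 with an estimated correlation.

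Splitting the same 8 samples in other ways bears on the counts. The knockout and wild-type split gave 15 changed genes and the highest of the other splits gave 18; with 2 of 35 splits as large, chance is not excluded for that count. At an unadjusted p under 0.05 it gave 5761 genes against 3680 at most in the others. With 1 of 35 splits as large, the smallest share possible, chance is unlikely for that count but not excluded. It gave 14 shifted lists against 16 at most in the others, and with 8 of 35 as large chance is not excluded there. With no filter on dim probes it gave 3522 genes against 5 at most in the others. Here too 1 of 35 splits was as large, so chance is unlikely for that setting but not excluded. Neither count excludes a difference between the slide rows.

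The 2432 genes called only with no filter were 93.9% higher in the knockout, and 98.1% of them sat on the surrogate floor of the processed signal on an array. True change of weakly expressed genes stays open: 0.164% of them kept their call and direction with normexp and no filter, and the median difference went from 0.45 to 0.11. At their median processed signal of 4.22 the normexp offset of 50 leaves 7.78% of a small fold, so this loss decides nothing. A higher floor on the knockout arrays goes with the data: negative control spots, which bind no transcript, were higher there by 0.47 ± 0.10 (SE) after the same scaling. What set the floor stays open, as slide row and genotype cannot be told apart.

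Ciliated and club markers were higher together with cardiac, smooth muscle and fat markers, which may reflect how much airway and heart tissue each sample held. More heart muscle as the source of the ciliated shift is not settled. With the cardiac score as a covariate that difference hardly moved, from 0.52 ± 0.20 to 0.51 ± 0.25 (SE). It lay only just beyond 2 SE of 0, which with 8 samples and a covariate does not tell it from 0. More large airway stays open: 9 cartilage markers differed by 0.24 ± 0.27 (SE), which neither shows nor excludes it. An effect of the genotype on airway cells also stays open, as untested.

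Less blood in the knockout samples is a candidate explanation for the lower monocyte markers. Whether it also bears on the lower inflammasome and cytokine lists was not tested. The platelet list, which less blood predicts to be lower too, differed by -0.85 ± 0.18 (SE, n = 4 per group, exact permutation p = 0.0286, the smallest possible). That list was chosen after Gp1ba and Ly6g6f had been seen to fall in the same samples, so its p is not independent support. Erythroid markers differed by -0.68 ± 0.38 (SE, exact permutation p = 0.143), in the same direction but within 2 SE of 0. The platelet and erythroid means did not move together in every sample. Wild-type replicate 4 had an erythroid mean of 3.32, below every knockout sample (3.33 to 3.93). Its platelet mean of 0.93 lay above every knockout sample (-0.16 to 0.12). Dilution by tissue that goes with the heart muscle score is argued against as the whole cause, since the monocyte difference was -0.73 ± 0.15 (SE) with that score as a covariate, against -0.62 ± 0.14 without. Dilution by tissue of another kind stays open: the change of the monocyte mean minus that of the endothelial mean was -0.52 ± 0.28 (SE), which lies within 2 SE of 0 and of the whole difference; an effect of the genotype on recruitment also stays open, as untested.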
